A study of Homo sapiens with 2 samples.

How the data were processed

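Total RNA of HS746T cells was labelled from 500 ng with biotin, per the labels' protocols, and hybridised to 2 PrimeView arrays, 1 of cells labelled GFI1 over-expression and 1 of wild type cells. Cells had been grown with 10% serum, per the labels. The deposited values are log2 expression values per probe set made by the authors with RMA, per the submitters' processing notes. RMA corrects the background of each array, forces the arrays to the same distribution and summarises the probes of a set into a single value. Its version and the number of arrays it was run on are not given in the sources used here. Forcing a common distribution removes any difference in total RNA per cell, and background correction squeezes differences of dim probe sets towards 0. Scanner files were not used here. The value table of the series and the deposited RMA table held the same numbers, with 0 of 49395 shared probe sets differing, and the second also held 100 ERCC control sets. Groups were taken from the title labels and columns from the sample they name.

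Gene symbols came from the annotation in the deposited table, which dates from 2013 and places targets on GRCh37. Of 49293 probe sets other than controls, 46240 named 1 gene symbol, 2640 named several and 413 named none; only the first kind was used for genes. Symbols were updated by Entrez identifier through the NCBI RefSeq gene table of GRCh38.p14, which was used for names alone and matched 46035 of them. Starts of alignments were raised by 1 base, since 8848 Ensembl transcripts with the same listed end start 1 base after the listed start and 628 at it. No genome was used, so positions of probes in exons or untranslated regions are not given.

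Each of 18574 genes was represented by the probe set with the highest mean of the 2 arrays. The floor of each array was the 95th percentile of 553 probe sets of genes that cultured tumour cells should not express (olfactory, taste and vomeronasal receptors, keratin-associated proteins and beta-defensins). A gene counted as at least 2-fold higher or lower where its log2 difference was at least 1 in size and its brighter array was above that array's floor. Where the dimmer array was not above its floor, the fold is given as at least the brighter value against the higher of the dimmer array's floor and its value. No test was run, because each group had 1 array, and the number of arrays limits the precision of every value. The spread between probe sets of one gene was 1.4826 times the median absolute deviation of the differences between the other sets and the main set, above the floor, divided by the square root of 2.

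Before the data were examined, 41 gene lists, the alternatives and the rule for named genes were fixed. The rule named GFI1 and GKN2; the 12 highest and 12 lowest genes past the 2-fold threshold whose probe sets above the floor all went one way, leaving out symbols without an assigned name; and, from each list, up to 4 members past the threshold with the largest differences, or up to 2 members above the floor where fewer than 2 had passed it. Some genes that the rule names are not reported here. A list's median over members above the floor was placed among the medians of 10000 random lists with the same number of genes in each of 10 bins of mean expression. This percentile describes the 2 arrays and is not a p-value. Lists with fewer than 5 members above the floor got no percentile.

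The steps were tested on simulated data made from the mean levels of the 2 arrays, with 200 genes changed, all of them well above the floor. Unchanged genes got the observed spreads, and changed genes got only the spread between probe sets. In the simulated comparison of GFI1 over-expression with wild type, over 9770 genes above the floor, 100% of the genes changed by 2.0 on the log2 scale and 100% of those changed by 1.5 were recovered, and 0 unchanged genes passed the threshold. A list of 42 genes with a simulated median of -0.35 came out at -0.32, below all of its random lists, and 5.5% of 200 random lists of 20 genes fell outside the central 95%. The full recovery and the absence of unchanged genes were near certain, since the changes lay far past the threshold and the simulated spreads were small. They check the steps alone and say nothing of genes near the floor. The simulation holds no spread between cultures. Alternatives were other summaries of probe sets, other floors, 2 other centrings of the differences (their median set to 0, and a loess curve with a span of 0.3 on the mean level), fold thresholds of 1.5 and 3, the mean of a list, and unmatched random lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.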

Results

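Gene expression was measured in HS746T cells, an established human gastric cancer line, on 2 Affymetrix PrimeView arrays, which read transcripts near their 3′ end with sets of short probes. One array held RNA labelled as coming from cells given the transcription factor GFI1 by lentivirus, and the other held RNA of wild type cells. The study was titled around GFI1 and the proliferation of these cells, and the comparison asks which transcripts differ between the cultures. With 1 array per group there was no replicate check, so no p-value or SD is given, and every difference describes these 2 arrays and not the conditions. Of 49293 probe sets other than controls, 43.2% were above the floor on the array labelled GFI1 over-expression and 43.0% on the wild type array. Such like shares are largely fixed by RMA, which forces the arrays to the same distribution. "Higher" and "lower" always refer to the array labelled GFI1 over-expression against wild type.

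GFI1 itself, a zinc finger repressor of transcription, was not higher in the array labelled GFI1 over-expression. Its first probe set read 5.05 there and 5.18 in wild type on the log2 scale, a difference of -0.12, and its second read 5.55 and 5.48, a difference of 0.073. Neither set was above the floor, which lay at 7.0 and 6.99. Both sets are annotated to GFI1 on chromosome 1, 92940322 to 92952482 on the minus strand of GRCh37. All 11 probes of the second set match 2 complementary DNA clones listed with a complete coding sequence, and 0 probes of the first set do. The vector's sequence is not given in the sources used here, so a copy without the part that the probes read would go unseen, and the probes then check nothing. Because the values do not show the over-expression that the label names, each direction in the text rests on the label alone. GFI1B, a close relative of GFI1 looked up after the values were seen, differed by -0.090.

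GKN2, which encodes a gastrokine secreted by the normal stomach lining, was lower in the array labelled GFI1 over-expression. Its 1 probe set, on chromosome 2 at 69172367 to 69180012 on the minus strand, read 5.94 there and 7.10 in wild type, a difference of -1.16. The wild type value was just above its floor and the other was below, so the difference is only bounded as at least 1.07-fold. Of 22 measured gastric mucosa markers, 4 were above the floor on either array. TFF1, which encodes another secreted stomach peptide, was higher by 1.81, or at least 2.04-fold. Of 18 intestinal markers, 0 were above the floor.

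Across all genes the arrays were alike. Of 9774 genes above the floor on at least 1 array, 75 were at least 2-fold higher and 20 at least 2-fold lower. In 37 of the 75 higher genes and 8 of the 20 lower genes the dimmer array was not above its floor, so that the fold is only bounded. Counting these by their bounds, 9 genes were at least 4-fold higher, 5 of them with both arrays above the floor, and 0 at least 4-fold lower. Averaging all probe sets of a gene gave 48 higher and 12 lower genes, and requiring both arrays above the floor gave 38 and 12. All probe sets above the floor went one way in each of the 36 higher and 9 lower genes that had more than 1. The log2 difference was within 0.5 of 0 for 94.2% of the genes above the floor, with a median of -0.0096. That the median lay near 0 was largely fixed by RMA, which forces the arrays to the same distribution. The spread between probe sets of the same gene, scaled to 1 set, was 0.11. It arises within the 2 arrays and leaves out the spread between cultures.

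**Figure D1:**
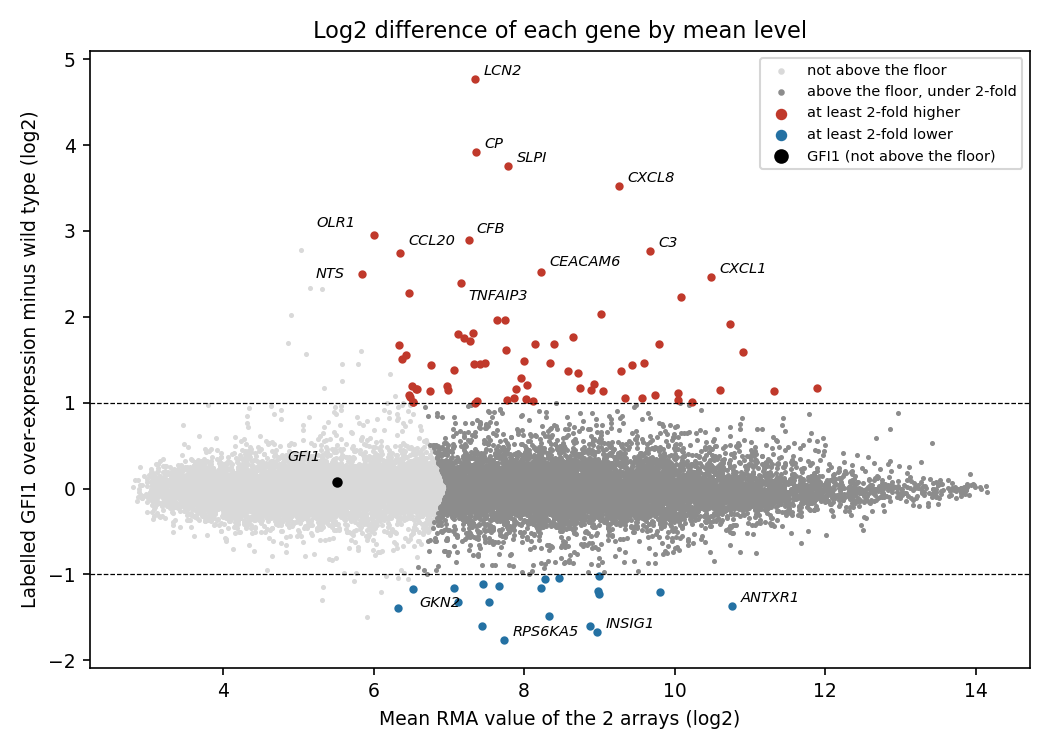
Each point is 1 gene, with the mean RMA value of the 2 arrays (log2) across and the log2 difference, array labelled GFI1 over-expression minus wild type, upwards; dashed lines mark 2-fold. The 75 red genes reach up to LCN2 at 4.77, the 20 blue genes reach down to RPS6KA5 at -1.76, and GFI1 (black) lies at 0.073.

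The 12 highest genes were taken by measured log2 difference, whatever the wild type level. Among them LCN2, which encodes an iron-scavenging antibacterial protein, read 9.73 against 4.96 in wild type, where it was not above the floor, or at least 6.68-fold. CP, which encodes the copper carrier ceruloplasmin, differed by 3.92, with its 4 probe sets between 3.10 and 3.92. SLPI, a secreted protease inhibitor, differed by 3.75. The neutrophil chemokine CXCL8, above the floor on both arrays, differed by 3.52, or 11.5-fold, and its 3 probe sets lay between 3.42 and 4.13. The complement genes CFB and C3 differed by 2.90 and 2.76, and the chemokines CCL20 and CXCL1 by 2.74 and 2.46. The other genes among the 12 highest were OLR1 (2.95), CEACAM6 (2.52), NTS (2.5) and TNFAIP3 (2.39). Wild type was not above its floor for 9 of them, where the fold is only a bound: at least 6.39-fold for SLPI, 5.61-fold for CEACAM6, 5.01-fold for CP, 3.29-fold for CFB, 2.56-fold for TNFAIP3 and 1.66-fold for CCL20. For OLR1 and NTS, close to the floor even in the brighter array, the bounds were 1.41-fold and 1.07-fold. The place of CEACAM6 rests on 1 probe set, since its 3 sets ranged from 0.79 to 2.52, and the 2 sets of TNFAIP3 lay at 1.66 and 2.39.

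The list of NF-kB and inflammatory genes was higher. Of its 22 members above the floor, 20 had a higher value and 10 were at least 2-fold higher, with a median of 0.66, while 95% of the medians of 10000 random lists of the same size and expression level lay between -0.11 and 0.090. Its mean was 1.31, with LCN2, CXCL8, C3 and CCL20 at the top. On the same array 3 probe sets with no alignment to the human genome were also higher, by at least 5.92-fold, 4.60-fold and 3.18-fold, with wild type not above its floor. The 18S ribosomal RNA control sets differed by a median of 1.03 and the 28S sets by -0.35. The list of interferon response genes had a median of 0.21, with 23 of 27 members above 0. IFI6, an interferon-induced membrane protein, was higher by 0.92, and HERC5, a ligase for ISG15, was lower, at -0.78. All 13 members of the antigen presentation list had a higher value, with a median of 0.19, a difference of 1.0 for HLA-C and of 0.71 for HLA-B. Random ranges were -0.10 to 0.10 and -0.14 to 0.12.

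Genes that cells induce at low oxygen were higher in the array labelled GFI1 over-expression. Of 24 hypoxia genes above the floor, 23 had a higher value, with a median of 0.41 against a random range of -0.10 to 0.079. DDIT4, an inhibitor of mTORC1, differed by 1.59, the vascular growth factor VEGFA by 1.44, ANGPTL4 by 1.29 and STC2 by 1.17. The 7 VEGFA probe sets above the floor ranged from 0.078 to 1.44. The glycolysis list had a median of 0.16, with differences of 0.55 for both the glucose transporter SLC2A1 and the lactate transporter SLC16A3. The unfolded protein response list, which shares DDIT4, VEGFA and STC2 with the hypoxia list, had a median of 0.099, and NUPR1, a stress-induced chromatin protein on it, was lower, at -1.60. The random ranges of these lists were -0.10 to 0.062 and -0.086 to 0.050.

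Epithelial genes were higher as a list, with a median of 0.30 over 14 members and a random range of -0.12 to 0.095, and without a floor the median was 0.11 over 31 members. The desmosome gene DSP differed by 1.0 and the keratin gene KRT8 by 0.88, with all 8 of its probe sets between 0.88 and 1.31. Another 17 epithelial members, EPCAM among them, were not above the floor in wild type and stayed below it on the other array. Mesenchymal genes went both ways, with a median of -0.051 inside the random range. Of these, LUM and SPARC, which encode matrix proteins, differed by -1.32 and -1.06 (from -1.06 to -0.19 over the 7 SPARC sets above the floor), while the fibronectin gene FN1 and the tenascin gene TNC differed by 1.13 and 1.09. The matrix proteases and inhibitors had a median of 0.026, inside the random range, although MMP7 differed by 1.92, and lay above it without a floor, at 0.10.

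Genes of mitosis were lower as a list in the array labelled GFI1 over-expression. Of 54 G2/M genes above the floor, 51 had a lower value, 45 of them by more than 2 spreads between probe sets and 0 by 2-fold, and the median was -0.42, below all 10000 random medians, 95% of which lay between -0.078 and 0.028. CKAP2, a spindle protein, differed by -0.76, with its 5 probe sets between -0.76 and -0.51, and the mitotic kinase gene AURKA by -0.75. G1/S genes differed less, with a median of -0.092 just outside the range of -0.087 to 0.046 and 27 of 40 members below 0. HELLS, a chromatin remodeller, differed by -0.70, and CCNE1, which encodes cyclin E1, by 0.65. This list came inside the range when all probe sets of a gene were averaged. Of 19 replication-dependent histone genes listed, 9 were measured and only 5 were above the floor. These 5 had a median of -0.32, against a wide random range of -0.22 to 0.23. Of these, H2AC6 differed by -0.49 and H2AC20 by 0.41, both close to the floor. The G1 cyclins and CDK inhibitors had a median of -0.11, inside the random range, with the CDK inhibitor gene CDKN1A at 0.57 and the cyclin gene CCND1 at 0.32.

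Sterol genes were lower as well. Of 22 genes of cholesterol synthesis and uptake, 17 had a lower value, and the median was -0.27 against a random range of -0.11 to 0.088. INSIG1, which holds back sterol synthesis, differed by -1.67, and its 3 probe sets lay between -1.67 and -1.25. NPC1, which is not on the list and carries cholesterol out of lysosomes, differed by -1.20 on 1 probe set and by -0.72 on the other. Fatty acid synthesis genes had a median of -0.20, with ACSL3 and SCD both at -0.55; averaging all probe sets gave -0.091, inside the random range. YAP/TAZ targets had a median of -0.32, with 15 of 20 below 0, but a mean of only -0.10, because IGFBP3, an insulin-like growth factor binding protein, differed by 2.24 and the tissue factor gene F3 by 1.20.

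Further genes among the 12 lowest were RPS6KA5 (-1.76), a kinase of histone H3, SPOCK1 (-1.60), ST6GAL2 (-1.48), PRDM1 (-1.40), ANTXR1 (-1.37), MCTP1 (-1.32) and PRTFDC1 (-1.19). The 3 probe sets of ANTXR1, an anthrax toxin receptor gene, lay between -1.53 and -1.37, and the 4 of PRTFDC1 between -1.23 and -1.19. The array labelled GFI1 over-expression was not above its floor for RPS6KA5, NUPR1, MCTP1, LUM and PRDM1, which were at least 3.06-fold, 2.37-fold, 2.28-fold, 1.72-fold and 1.01-fold lower. The same holds for HERC5 and SPRY2, at least 1.30-fold and 1.23-fold lower, and wild type was not above its floor for CHGB, F3, AXIN2 and TNC, at least 1.41-fold, 1.08-fold, 1.03-fold and 1.02-fold higher.

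Genes known to be repressed by GFI1 did not have lower values as a list. Their median was 0.10 over 16 members, 9 of them above 0, at the edge of the random range of -0.12 to 0.096, and without a floor it was -0.027. BAK1, a promoter of cell death, differed by 0.62 and CDKN1A by 0.57. The partners of GFI1 in its corepressor complex had a median of -0.056, inside the range, with AJUBA at -0.38 and ZMYM3 at 0.33. The p53 target list had a median of 0.17, with 18 of 26 members above 0 and BTG2, an antiproliferative gene, at 1.04. For the BCL2 family the median was 0.17, with BAK1 at 0.62 and PMAIP1 at 0.54. TGF-beta targets had a median of 0.16, with TGFBI at 0.70, and Wnt targets a median of 0.15, with AXIN2 at 1.01 and BMP4 at 0.92. These 4 lists lay above their random ranges. The BCL2 family and Wnt lists came inside them with at least 1 other summary of probe sets.

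**Figure D2:**
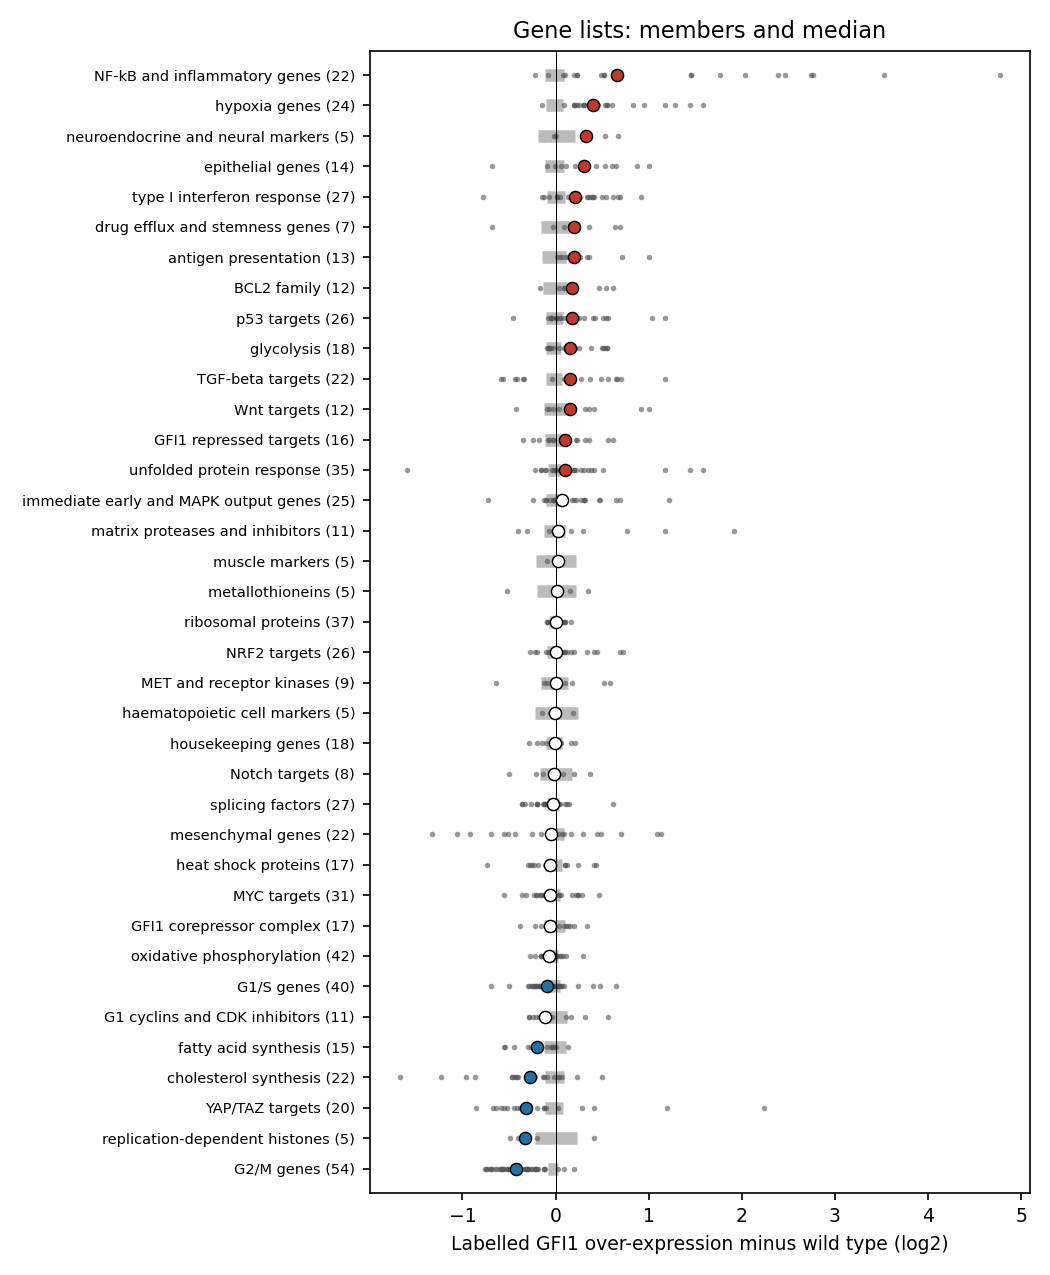
Each row is a gene list with its number of members above the floor, small points are members by log2 difference (array labelled GFI1 over-expression minus wild type), grey bars hold 95% of 10000 random medians, and large points are medians, red above, blue below and white inside the bar. Of 37 lists, 14 lay above and 6 below, from G2/M genes at -0.42 to NF-kB and inflammatory genes at 0.66.

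In all, 14 lists lay above and 6 below the central 95% of their random lists, where 1.9 of 37 would do so by chance, and 17 lay inside, 3 of which lay above it under at least 1 alternative. Genes that work together vary together, so random lists understate the range that a list of linked genes can take. Above it were also 5 neuroendocrine and neural markers, with a median of 0.33, CHGB at 0.67 and ENO2 at 0.53, and 7 drug efflux and stemness genes, with a median of 0.20, ABCC3 at 0.69 and ABCG2 at -0.68. Without a floor the neuroendocrine median was 0.012. Inside it were immediate early and MAPK output genes at 0.072, with JUN at 1.22 and SPRY2 at -0.72, and receptor kinases at 0.0033, with AXL at -0.64 and EPHB2 at 0.59. The immediate early list lay above the range under 4 alternatives, but for both centrings the random draw alone could account for that. MYC targets lay at -0.054, heat shock proteins at -0.054, Notch targets at -0.014, NRF2 targets at 0.0048 (0.044 and above it with the median over probe sets), metallothioneins at 0.014, oxidative phosphorylation genes at -0.066, ribosomal proteins at 0.0095, splicing factors at -0.030, haematopoietic cell markers at -0.0029, muscle markers at 0.025 and housekeeping genes at -0.0046. Long noncoding RNAs and endothelial markers had 4 and 2 members above the floor, too few for a percentile, with EGFL7 at 0.48 and MALAT1 at 0.32, whose 3 probe sets ranged from -0.66 to 0.32. The arrays also differed in a control of RNA quality: the ACTB set near the 5′ end minus that near the 3′ end was -0.64 on the array labelled GFI1 over-expression and -1.18 in wild type, while the 5′ set of GAPDH differed by -0.0059. Whether this bears on the lists was not tested.

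**Figure D3:**
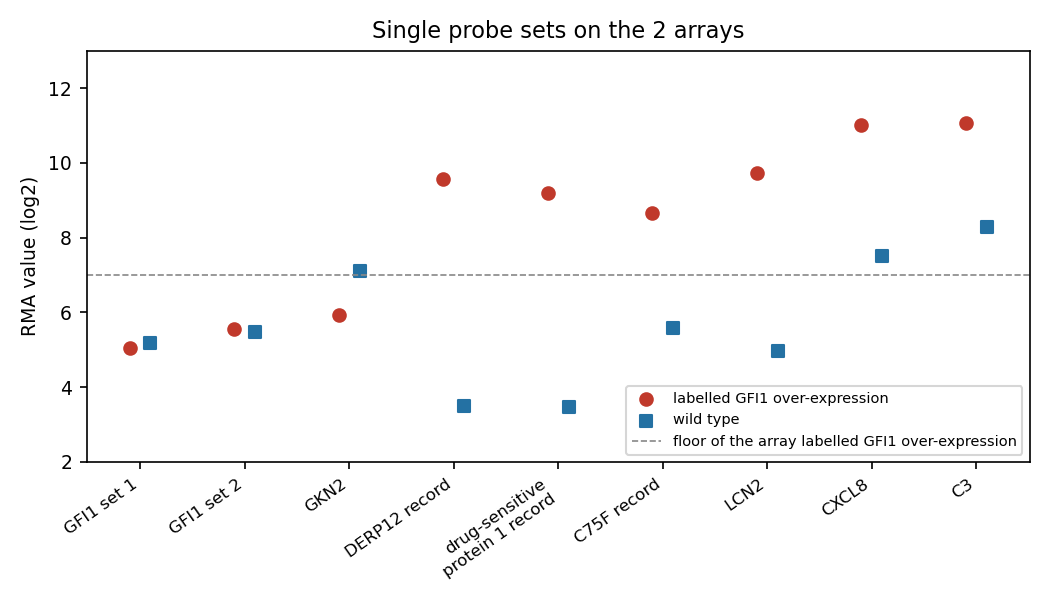
RMA values (log2) of single probe sets on the array labelled GFI1 over-expression (red circles) and on the wild type array (blue squares), with the floor of the former dashed. The GFI1 sets lie below the floor on both arrays, GKN2 crosses it, and 3 sets with no alignment to the human genome, named by their target records, read 9.56, 9.20 and 8.66 against 3.49, 3.48 and 5.58.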

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

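Every test in this part was chosen only after the result was seen, except that of epithelial cells. The 3 probe sets with no alignment to the human genome and the 18S ribosomal control sets lie outside the gene comparison and gave more signal in the array labelled GFI1 over-expression than in wild type. The set for the DERP12 record read 9.56 against 3.49, that for drug-sensitive protein 1 read 9.20 against 3.48, and that for the C75F record read 8.66 against 5.58. The first 2 carry an oxidoreductase annotation. Wild type was not above its floor for these 3 sets, so the folds are bounds, at least 5.92-fold, 4.60-fold and 3.18-fold. The other 184 sets without an alignment differed by at most 0.75 in size, with a median of 0. The median of 3 control sets for 18S ribosomal RNA was 12.2 against 11.2, while that of 28S ribosomal RNA was lower, at 9.47 against 10.4. Both 28S medians are from the set that differed most, by -0.89, and the other sets differed by -0.35 and -0.053.

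The inflammatory genes were higher on the same array as these sets. A mixture with epithelial cells of another kind was tested on the 17 epithelial list members not above the floor in wild type. Of these, EPCAM among them, 0% were higher by at least 1. This argues against a large share of cells that express the common epithelial markers. A small share stays open, because background correction squeezes differences of dim probe sets towards 0. The 14 list members above the floor had a median of 0.30, which goes with epithelial cells mixed in. Cells that lack the 17 markers also stay open. RNA of another organism, such as a bacterium growing in the culture, stays open: the 3 sets above the floor on that array alone prompted this explanation, so their count does not test it. The organism of these targets and any effect on the inflammatory genes were not tested, and vector sequence stays open since the vector is not given. GFI1 or the viral transduction also stays open, because the largest difference of a GFI1 probe set was 0.073 and no array of cells with an empty vector was analysed here, so that transduction and group cannot be told apart.

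The G2/M genes were lower by a median of -0.42. A level-dependent shift between the arrays is argued against as the whole cause, since random lists of genes of the same expression level, which such a shift moves alike, had a central 95% of medians of -0.078 to 0.028, and the list lay -0.39 from their median. Loess centring moved little, with a curve between -0.030 and 0.0062, and tests nothing here. A GC-dependent shift stays open: the antigenomic background probe sets, which match no human sequence, differed over a span of 0.25, from -0.033 to 0.21 at the most GC-rich, so no GC class came near -0.42. Most of these sets read below the floor, with medians of 3.72 and 3.68. The most GC-rich lay above it, up to 11.1 against 10.8, and were higher, opposite to the list. Sets of lower GC content bound no shift of brighter probes, and the GC content of the list's probes is not known here. The difference that the labels name, GFI1 or transduction, stays open and untested.

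GFI1 was not higher in the array that carries its name. The prediction for probes outside the part of GFI1 in the vector was that no set matches coding sequence clones. All 11 probes of the second set match them, so this prediction was not met, and that set differed by 0.073. A vector that lacks what these probes read stays open, since what the vector holds is not given. A swap of the 2 arrays is not shown either, since the lowest GFI1 difference was -0.12, far from the opposite of an over-expression, and a swap with probes that miss the vector would look the same. That GFI1 RNA was not raised in this culture also stays open.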

How the results depend on the processing

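All alternatives in this part were fixed before the data were examined. No paired analysis was possible because each group had 1 array; leaving out a replicate and other splits of the samples were not possible for the same reason. The 2 deposited tables held identical values, so exchanging them gave no other value. For GFI1 the median over probe sets above the floor and the floor on both arrays gave no value, nor did the latter for GKN2; the other alternatives left both within the spread between probe sets of 0.11. Of 40 named genes past the 2-fold threshold, other than GFI1 and GKN2, 262 of 262 alternative values kept their sign and 244 stayed at least 2-fold. Of all 644 alternative values of named genes, 564 moved by less than the spread. These counts were largely fixed in advance. The other floors leave a gene's value as it was, and the loess curve takes off only -0.030 to 0.0062. Only the other summaries of probe sets could move a value far, and none could for GKN2, with 1 probe set. Genes among the 12 highest and 12 lowest were also picked for probe sets that went one way. Signal over background limits the folds of 37 of the 75 higher and 8 of the 20 lower genes, whose dimmer array was not above its floor. Genes at least 2-fold higher and lower numbered 89 and 28 without a floor, 79 and 25 with the floor at the median of all probe sets, 48 and 12 with the mean over all probe sets, 38 and 12 with both arrays above the floor, and 36 and 9 with 2 or more agreeing probe sets. At 1.5-fold they numbered 237 and 153, and at 3-fold 29 and 4. With the mean over all probe sets, 56 of 60 genes were shared with the 95 reported. Of the 20 lists outside the central 95%, 14 stayed on their side under each alternative of probe sets, floor and centring, tested with 2000 random lists each, that gave a value, and 19 against unmatched lists. Histones, 1 of these 14, had too few members for a value with the mean over all probe sets, as did neuroendocrine markers there and with both arrays above the floor. The exceptions were G1/S genes (percentiles 3.15 and 5.45 with the mean and the median over probe sets), Wnt targets (97.4 with the mean, 95.4 without a floor), fatty acid synthesis (10.2 with the mean), the BCL2 family (96.2 with the median over probe sets), neuroendocrine markers (68.7 without a floor), and GFI1 repressed targets (36.5 without a floor, 96.2 with the floor at the median, 97.4 with loess, 97.1 unmatched). Of the 17 lists inside, 3 lay above the range in an alternative: immediate early genes (percentiles 99.7 with the mean and 100 with the median over probe sets, 97.8 with the median difference set to 0, 97.7 with loess), NRF2 targets (98.5 with the median over probe sets) and matrix proteases (99.7 without a floor). Of 289 alternative list medians, 197 moved by at most the spread between probe sets divided by the square root of the number of members. The cause was not tested for the others, which follow.

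With the mean over all probe sets of a gene, medians were 0.13 for GFI1 repressed targets, -0.027 for GFI1 corepressor complex, -0.034 for G1 cyclins, 0.23 for BCL2 family, 0.10 for matrix proteases, 0.27 for antigen presentation, 0.60 for inflammatory genes and 0.14 for immediate early genes. The others there were 0.042 for receptor kinases, -0.22 for YAP/TAZ targets, -0.11 for heat shock proteins, 0.53 for hypoxia genes, -0.34 for cholesterol synthesis, -0.091 for fatty acid synthesis, -0.071 for splicing factors and 0.28 for drug efflux genes. Without a floor they were -0.027 for GFI1 repressed targets, -0.057 for G1 cyclins, 0.11 for epithelial genes, 0.10 for matrix proteases, 0.17 for interferon response, 0.16 for antigen presentation, 0.49 for inflammatory genes and 0.027 for immediate early genes. The others there were 0.082 for receptor kinases, 0.063 for Wnt targets, 0.11 for glycolysis, -0.20 for histones, 0.047 for haematopoietic markers, 0.012 for neuroendocrine markers and 0.12 for drug efflux genes. Means of lists in place of medians were -0.0088 for GFI1 corepressor complex, -0.071 for G1/S genes, -0.40 for G2/M genes, -0.018 for G1 cyclins, 0.22 for p53 targets, 0.22 for BCL2 family, 0.32 for matrix proteases and 0.24 for interferon response. The others there were 0.28 for antigen presentation, 1.31 for inflammatory genes, 0.16 for immediate early genes, 0.054 for receptor kinases, -0.10 for YAP/TAZ targets, 0.23 for Wnt targets, 0.17 for unfolded protein response and 0.55 for hypoxia genes. The last were 0.20 for glycolysis, -0.35 for cholesterol synthesis, 0.090 for NRF2 targets, -0.20 for histones and -0.063 for splicing factors. With the median over probe sets above the floor, medians were -0.074 for G1/S genes, 0.13 for p53 targets, 0.12 for BCL2 family, 0.11 for matrix proteases, 0.28 for antigen presentation, 0.92 for inflammatory genes, 0.22 for immediate early genes and 0.046 for receptor kinases. The others there were -0.29 for YAP/TAZ targets, 0.19 for TGF-beta targets, 0.20 for Wnt targets, 0.12 for unfolded protein response, -0.11 for heat shock proteins, 0.19 for glycolysis, -0.33 for cholesterol synthesis and 0.044 for NRF2 targets. The last were -0.052 for splicing factors and 0.26 for drug efflux genes. With the median difference set to 0 it was -0.40 for G2/M genes. After loess centring they were -0.39 for G2/M genes, 0.10 for immediate early genes, -0.29 for YAP/TAZ targets, 0.18 for TGF-beta targets, 0.13 for unfolded protein response, -0.25 for cholesterol synthesis, 0.026 for NRF2 targets and -0.040 for oxidative phosphorylation. The last was -0.0081 for splicing factors. With the floor at the median of all probe sets they were -0.080 for mesenchymal genes, 0.094 for matrix proteases, 0.16 for antigen presentation, 0.63 for inflammatory genes, 0.43 for hypoxia genes and 0.25 for neuroendocrine markers. With both arrays above the floor they were -0.027 for mesenchymal genes, 0.52 for inflammatory genes, -0.36 for YAP/TAZ targets, 0.38 for hypoxia genes, -0.30 for cholesterol synthesis and -0.14 for fatty acid synthesis. Of the 20 lists outside the central 95%, GFI1 repressed targets alone turned sign, without a floor.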

Other observations

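The gene groups in this part were picked after the values were seen, from a scan of 1237 biological process terms in the array's own annotation with 10 to 200 genes above the floor. Of these, 163 lay above and 77 below the central 95% of 1000 matched random lists each, where 30.9 on each side would do so by chance; many terms share genes. The complement activation term had the highest median, 0.77 over 10 genes. Besides CFB and C3, the factor D gene CFD was higher in the array labelled GFI1 over-expression by 1.69, C1R by 1.15 and C1S by 0.82, while C5 was lower, at -0.84. The term for the response to vitamin D had a median of 0.53 over 11 genes, with the cyclooxygenase gene PTGS2 at 2.03, the water channel gene AQP3 at 1.75, SPP1 at 0.82 and CYP24A1, which breaks down vitamin D, at 0.53. Regulation of proteolysis had a median of 0.58 over 11 genes, led by SERPINA3 at 1.72. For most genes named only in this part it is not given whether both arrays were above the floor, so their differences are not to be read as folds.

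Among single genes, LAMB3, a chain of laminin-332, differed by 1.96 and ITGB4, an integrin chain, by 1.68. The urea cycle gene ASS1 differed by 1.61, and CPS1 read 8.74 against 7.26 in wild type. At the other end, the spindle organization term had a median of -0.32 over 19 genes, mitotic chromosome condensation -0.30 over 13 genes, and sterol biosynthesis -0.23 over 23 genes, with HMGCS1 at -0.96. The receptor kinase gene MET differed by 0.10, at 11.9 against 11.8.

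The actin control set near the 5′ end of ACTB was higher by 0.58 in the array labelled GFI1 over-expression, while the set near its 3′ end differed by 0.035. Hybridisation spikes had a median difference of 0.0087. The 12 poly(A) spike sets had a median difference of 0.13, ranging from -0.24 to 0.38, with median levels of 5.37 and 5.43, below the floor. The dap-3 and dap-M sets among them, above the floor on both arrays, differed by 0.36 and 0.38.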
